A study of Sus scrofa with 4 samples.

How the data were processed

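RNA of pig kidney was measured by sequencing in 4 libraries, 1 for each of 4 groups. The groups combine 2 genotypes with 2 states of the kidney. In the first genotype, called CD39/CD55 in the text, the pigs lacked the galactosyltransferase GGTA1, which makes the alpha-Gal sugar antigen, and carried human CD39 and CD55. In the second, called CD39/CD46/CD55/TBM, they also carried human CD46 and thrombomodulin (TBM). Kidneys were either untransplanted or taken after transplantation into non-human primates, 4 weeks after transplantation in CD39/CD55 and 6 weeks after in CD39/CD46/CD55/TBM. Genotype, weeks after transplantation, recipient and any preparation batch therefore cannot be told apart within the transplanted pair. Whether a transplanted and an untransplanted kidney came from the same animal is not given in the sources used here.

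The deposited files hold raw counts of reads per gene, as whole numbers that sum to a different total in each library, and the authors applied no normalization to them. Per the labels' protocols, total RNA was extracted with phenol and chloroform and made into libraries with a Lexogen QuantSeq kit. Kits of that name usually read the 3' ends of polyadenylated transcripts, and counts per gene do not show which part of a transcript was read. The catalogue number printed beside the kit's name may belong to another Lexogen kit, so whether the counts are of 3' ends or of whole transcripts is not settled here. Bowtie2, bedtools and the genome build Sscrofa11.1 are named per the submitters' processing notes. Their versions, parameters, the handling of reads that match several genes and the use of strand in counting are not given in the sources used here. Reads shared by near-identical or overlapping genes can then be split or counted more than once, so values of SLA class I genes, MT1A and MT1D, and the ribosomal RNA loci are uncertain, as are those of any gene with an overlapping or antisense neighbour. No unique molecular identifiers are mentioned, so intervals and floors cover counting error only. How reads of the primate recipient were treated is not given in the sources used here. They may have been counted in pig genes where the sequence matched or lost where it did not.

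Each file had 26965 lines and 26466 gene symbols, all of which are in the RefSeq gene table of Sscrofa11.1. Lines of the 81 symbols that occur more than once, B2M, C4BPA and RPL18 among them, were summed. Of the symbols, 9842 are provisional LOC names and 3369 had no count in any library. Among 16077 lines with a total of at least 50 counts, 12 had the same 4 counts as another line. The lowest Spearman correlation of counts between any pair of libraries was 0.93, and no library was a copy of another. Coordinates in the text are those of the RefSeq table, which uses the same build.

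The total count was 14092905 in the untransplanted CD39/CD55 kidney, 11566041 in the transplanted CD39/CD55 kidney, 13226372 in the untransplanted CD39/CD46/CD55/TBM kidney and 10346863 in the transplanted CD39/CD46/CD55/TBM kidney. A floor of 3 counts, the upper limit that a count of 0 allows, corresponds in the same order to 0.218, 0.242, 0.237 and 0.29 scaled CPM.

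Genes with at least 10 counts in 1 or more libraries were kept, which left 18168. Counts were scaled by the TMM factors of edgeR, 0.975, 1.07, 0.957 and 1.00 in the order above. For each pair of libraries the log2 ratio of scaled counts was computed with a prior count of 0.5, together with an exact 95% interval (Clopper-Pearson, conditional binomial). A gene was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. This rule compares 2 libraries, not 2 conditions. With 1 library per group, these comparisons have no replicate check, and no p-value or standard error is given for them. For a gene with no count in 1 library, the fold is a lower bound against the floor of 3 counts in that library. The difference of the transplantation changes between the genotypes is the log2 ratio of the 2 ratios over 4 libraries, with a 95% Wald counting interval and the same rule.

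In the comparison of transplanted with untransplanted kidney over both genotypes, and in that of the genotypes over both states, each side had 2 libraries. These were tested with edgeR's quasi-likelihood test with 2 residual degrees of freedom, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the test's F statistic. It restates the result of the test and is no separate estimate of spread. The libraries of a side differ in genotype or in state, so the spread in this test holds those differences as well, and nothing in the labels says how many animals a genotype had. The words rose and fell are used only of genes past this threshold. Alternatives were DESeq2's size factors, DESeq2's Wald test, limma voom, the other factor as a block, no filter on counts, and leaving out each library in turn. For the ratios they were 2 other scalings, no filter, a filter of 50 counts, a rule of 4-fold, a rule that the whole interval lies beyond 2-fold, and counts thinned to 10346863 per library. For the lists they also included a prior count of 5.

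Groups, tests, alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists held 852 distinct symbols, of which 816 were in the files and 723 were tested. To reach them, 18 symbols were looked up under another name, so that GGTA1 appears as GGTA1P, G6PC1 as G6PC, KIRREL1 as KIRREL and CCN1 as CYR61. A list was described if at least 5 of its members were measured, which held for 31 lists and not for the neutrophil and urothelium markers. For each list the median log2 ratio, its percentile among 10000 random lists of the same size drawn from the same 10 bins of mean expression, and the numbers of members called are given. The percentile describes these libraries and is no test of the condition. Where a member has no count in a library, its fitted ratio is no bound, and the median with such members at their bound is given if it differs.

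Named genes were, per pair of libraries, the 8 with the highest and the 8 with the lowest near end of the interval among the called genes. Per list, up to 2 called members in each direction were added for each pair and for the difference of changes. Per test of 2 against 2 libraries, the 10 with the smallest p in each direction among those past the threshold were added, or the 5 with the smallest p if fewer than 5 pass. Provisional LOC names were left out of the choices by pair and by test. Genes that the design named in advance are given whatever their values, and some genes that the rule names are not reported here. These are the pig genes matching the modifications and common markers of injury, immune cells, matrix and nephron segments. Genes with fewer than 10 counts in every library were named only in that last group.

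R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Both kinds of comparison were tested on simulated data with 200 changed genes among 18168. The changed genes were drawn only from genes above a minimum mean expression, so recovery of genes with low counts was not measured. For transplanted against untransplanted kidney over both genotypes, at a dispersion of 0.1, edgeR recovered 69% of the genes changed 4-fold and 100% of those changed 16-fold, and called 4 unchanged genes. The estimated dispersion of the real data was 0.139. For the ratio of the CD39/CD55 pair, drawn with counting error alone, 100% of genes changed 4-fold were recovered, the 95% intervals held the true ratio for 95.8% of genes, and 0.596% of unchanged genes were called.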

Results

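Gene expression was measured by RNA sequencing in kidneys of genetically modified pigs, either untransplanted or taken after transplantation into non-human primates. There were 4 libraries, 1 in each of 4 groups. The series was designed to choose between 2 donor genotypes by how well each eases immune rejection. CD39/CD55 pigs lacked the galactosyltransferase GGTA1 and carried human CD39 and CD55. CD39/CD46/CD55/TBM pigs also carried human CD46 and thrombomodulin. CD39 degrades extracellular ATP and ADP, CD46 and CD55 restrain complement, and thrombomodulin activates the protein C pathway against clotting. The transplanted CD39/CD55 kidney was taken 4 weeks after transplantation and the transplanted CD39/CD46/CD55/TBM kidney 6 weeks after. With 1 library per group there is no replicate check for any single pair.

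Total counts were 14092905 and 11566041 in the untransplanted and transplanted CD39/CD55 kidneys, and 13226372 and 10346863 in the untransplanted and transplanted CD39/CD46/CD55/TBM kidneys. At least 1 count was found for 21104, 21294, 21200 and 21392 genes in the same order. Loci of ribosomal RNA took 10.7% and 22.4% of counts in CD39/CD55 and 12.6% and 18.9% in CD39/CD46/CD55/TBM. The share was thus higher in the transplanted kidney of both genotypes. RN18S, LOC110258600 and LOC110258214 held near-equal counts within each library, such as 409004, 412917 and 409648 in the untransplanted CD39/CD46/CD55/TBM kidney. The same reads may therefore have been counted at more than 1 of these loci, which would make the ribosomal RNA shares and the total counts too high. The 13 mitochondrially encoded genes took 10.6% and 4.23% of counts in CD39/CD55 and 15.0% and 12.6% in CD39/CD46/CD55/TBM. Ribosomal protein genes took 7.16% in the transplanted CD39/CD55 kidney and between 4.24% and 4.53% in the other 3 libraries. The 10 most abundant genes took from 20.8% of counts in the untransplanted CD39/CD55 kidney to 31.7% in the transplanted CD39/CD46/CD55/TBM kidney. The exact 95% binomial intervals (Clopper-Pearson) of these shares extended at most 0.0284 percentage points to either side.

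The pig genes matching the modifications were examined first. GGTA1P, the symbol of the galactosyltransferase gene in the files (chromosome 1, 261511304 to 261587968, Sscrofa11.1), had 291 and 303 counts in CD39/CD55 and 316 and 312 in CD39/CD46/CD55/TBM. Both genotypes carry its loss, so no unmodified library serves as a reference. Reads outside the edited part of the gene check nothing about the edit, and which part was edited is not given in the sources used here. Human transgene reads may or may not fall on the pig genes, so the pig genes ENTPD1 (CD39), CD46, CD55 and THBD do not measure the transgenes. Between the untransplanted kidneys, CD46 had 860 and 716 counts, CD55 39 and 28, and ENTPD1 286 and 278, with log2 ratios of -0.15, -0.35 and 0.08. THBD (chromosome 17, 30219870 to 30223499), the pig thrombomodulin gene, had 200 counts in the untransplanted CD39/CD55 kidney and 102 in the untransplanted CD39/CD46/CD55/TBM kidney, a log2 ratio of -0.85 (95% counting interval -1.21 to -0.50). After transplantation it had 16 and 65 counts. CD46 had 1036 and 1412 counts after transplantation, CD55 27 and 60, and ENTPD1 153 and 255.

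Transplanted and untransplanted kidneys were compared over both genotypes, 2 libraries against 2. Among the genes that fell were 21 of 46 measured proximal tubule genes. Among those that rose were 10 of 35 tubular injury and 10 of 38 interferon response genes. SLC5A12, a monocarboxylate transporter of the proximal tubule (chromosome 2, 33560988 to 33613548), fell from 15065 to 220 counts in CD39/CD55 and from 15005 to 141 in CD39/CD46/CD55/TBM, a log2 fold change of -6.18 (SE 0.58, adjusted p = 0.000631). SPP1, which encodes osteopontin (chromosome 8, 131077786 to 131085334), rose from 877 to 17836 and from 597 to 25798 counts, a log2 fold change of 5.15 (SE 0.61, adjusted p = 0.00124). The protease gene MMP7 rose by 4.31 (SE 0.48, adjusted p = 0.00098). In edgeR's quasi-likelihood test 225 genes rose and 493 fell among 18168. At an unadjusted p under 0.05 there were 1633 and 1946. The counts moved by over 1.5 times under DESeq2's Wald test (431 and 865), with genotype as a block (1124 and 1681), without a filter (543 and 1035) and without the transplanted CD39/CD55 library (1055 and 1374), and without the untransplanted CD39/CD46/CD55/TBM library 371 genes rose.

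Besides SPP1 and MMP7, the genes with the smallest p among those that rose were S100A2, REG3G, DEFB115, ADAMDEC1, C7H6orf222, GRM3, APOD and FGB. REG3G, a secreted antimicrobial lectin, went from 4 to 443 counts in CD39/CD55 and from 0 to 1170 in CD39/CD46/CD55/TBM, where it was at least 477-fold higher (adjusted p = 0.00098). S100A2 rose from 11 to 370 and from 9 to 789 counts. ADAMDEC1 rose from 30 to 2102 and from 30 to 466, and the apolipoprotein gene APOD from 231 to 2020 and from 139 to 1503. Those that fell with the smallest p were SLC5A12, CYP2D25, C1QC, GATM, MT1D, SLC12A3, SLC22A6, C1QB, PROC and NEIL1. GATM, an enzyme of creatine synthesis, fell from 4355 to 150 and from 6889 to 56 counts. SLC12A3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule, fell from 2934 to 81 and from 3094 to 23. The organic anion transporter SLC22A6 had 272 and 4 counts in CD39/CD55 and 543 and 0 in CD39/CD46/CD55/TBM, where it was at least 148-fold lower. Counts of the metallothionein gene MT1D fell from 24001 to 509 and from 16075 to 209, and may include reads of its near copy MT1A.

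Proximal tubule genes were low in both transplanted kidneys. Of 46 measured members, 21 fell and none rose in the test over all genes, and 34 fell when adjusted over the list alone. LRP2, which encodes the endocytic receptor megalin (chromosome 15, 75565299 to 75754604), fell from 23515 to 2622 and from 20999 to 831 counts, a log2 fold change of -3.53 (SE 0.60, adjusted p = 0.00825). The median log2 ratio of the list was -2.11 in CD39/CD55, where 33 members were called lower and none higher, and -2.20 in CD39/CD46/CD55/TBM, where 40 were called lower and none higher. Fatty acid oxidation and peroxisome genes, which fuel this segment, had medians of -1.36 and -2.0, and 11 of 28 fell (18 adjusted over the list alone). The carnitine carrier SLC25A20 fell by 2.89 on the log2 scale (SE 0.49, adjusted p = 0.00788) and PECR by 2.43 (SE 0.48, adjusted p = 0.0155). Nuclear oxidative phosphorylation genes had medians of -1.09 and -0.73, and none of 36 passed the test in either adjustment. The medians of the proximal tubule and fatty acid oxidation lists lay below every matched random list in both genotypes.

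Other nephron segments and the glomerulus were compared in the same way. Among thick ascending limb and distal convoluted tubule genes, 6 of 26 fell and none rose (9 and 0 adjusted over the list alone), with medians of -0.95 in CD39/CD55 and -0.57 in CD39/CD46/CD55/TBM. UMOD, uromodulin of the thick ascending limb, had 45070 and 6945 counts in CD39/CD55 and 15092 and 2214 in CD39/CD46/CD55/TBM, with an adjusted p of 0.0529. Collecting duct genes had medians of 0.31 and 0.42, and none of 26 passed the test in either adjustment. The water channel gene AQP2 had 14 and 17 counts in CD39/CD55 and 27 and 2 in CD39/CD46/CD55/TBM. Podocyte and glomerulus genes had medians of -0.83 and -0.48, and of 22 members 4 fell and none rose, and adjusted over the list alone 5 fell and 1 rose. NPHS1, which encodes nephrin of the filtration slit, fell from 232 to 21 and from 116 to 19 (log2 fold change -2.88, SE 0.54, adjusted p = 0.0129).

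**Figure D1:**
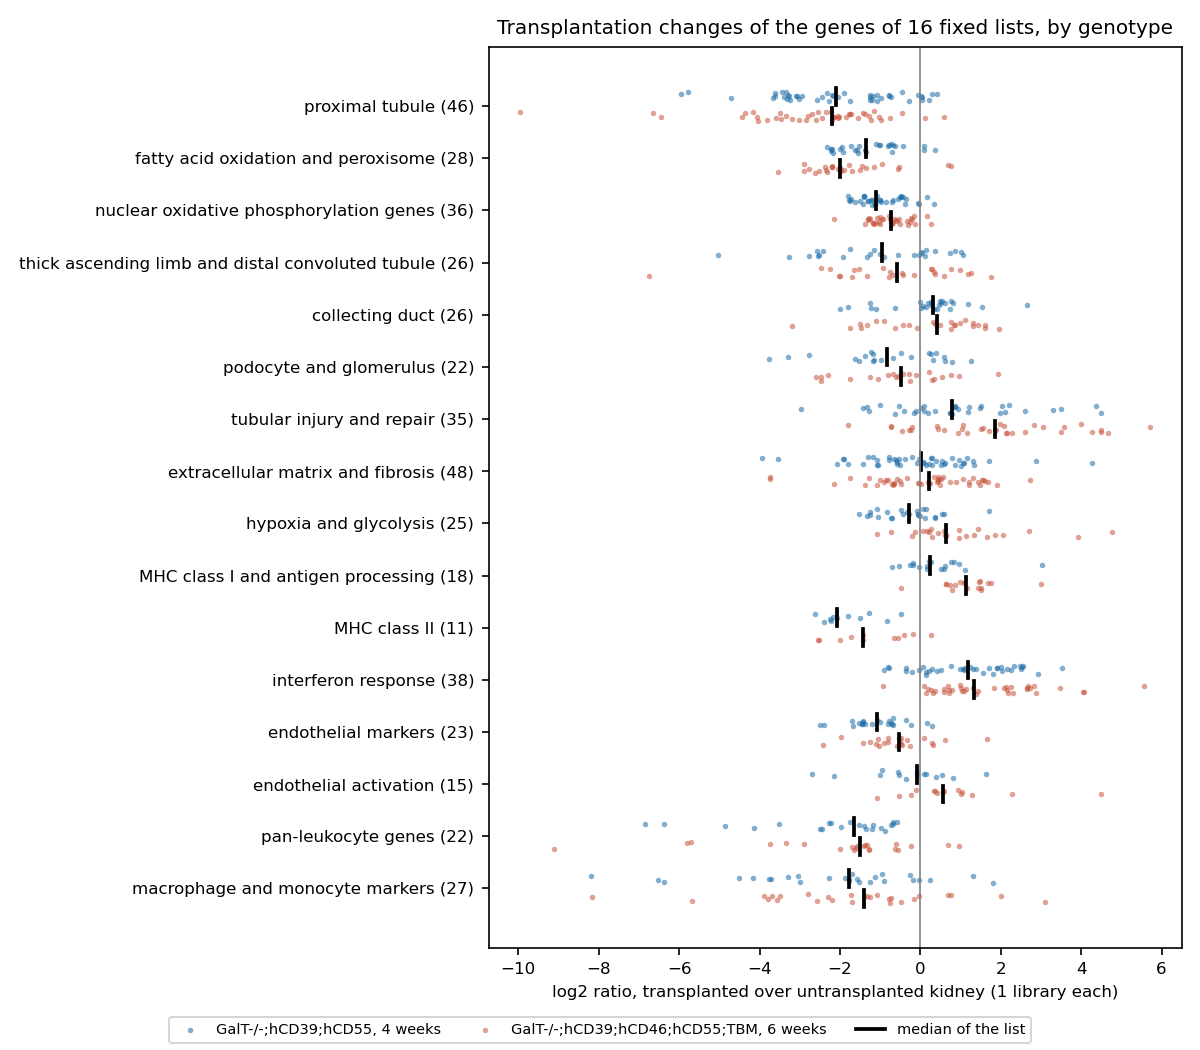
Log2 ratio of transplanted over untransplanted kidney (x axis) for the measured genes of 16 lists (y axis, number of genes in brackets), as points, with the median of each list as a black bar, in CD39/CD55 (blue) and CD39/CD46/CD55/TBM (red), 1 library each. The proximal tubule medians lie at -2.11 and -2.20 and the tubular injury medians at 0.79 and 1.84, and a gene without a count in 1 library is drawn at a ratio set by the prior count of 0.5.

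Tubular injury and repair genes were high after transplantation. In the test over all genes, 10 of 35 rose and none fell, and adjusted over the list alone 16 rose and 2 fell. CLU, which encodes the chaperone clusterin, rose from 1314 to 5074 and from 1025 to 21240 counts (log2 fold change 3.80, SE 0.71, adjusted p = 0.013). The stress gene NUPR1, named by its size of change and on no list, rose by 3.39 (SE 0.58, adjusted p = 0.00841). LCN2, an early marker of tubular damage, had 42 and 63 counts in CD39/CD55 and 19 and 255 in CD39/CD46/CD55/TBM, with an adjusted p of 0.0517. HAVCR1, another injury marker, had 6 counts or fewer in every library. The list's median was 0.79 in CD39/CD55 and 1.84 in CD39/CD46/CD55/TBM.

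Interferon response genes were also high. Of 38 measured, 10 rose and none fell (15 and 0 adjusted over the list alone), and 21 and 23 were called higher in the 2 genotypes with none lower. The median was 1.18 in CD39/CD55 and 1.34 in CD39/CD46/CD55/TBM, both above every matched random list. The chemokine gene CXCL10 (chromosome 8, 71693641 to 71695948) rose from 75 to 256 and from 12 to 481 counts (log2 fold change 3.38, SE 0.70, adjusted p = 0.0199). IFI6 rose by 3.14 (SE 0.48, adjusted p = 0.0046) and OAS2 by 2.42 (SE 0.45, adjusted p = 0.0127). CXCL9 had 3 to 6 counts in each library and IDO1 at most 1, so differences were not detectable at this depth. Of 18 MHC class I and antigen processing genes, 1 rose (the same number adjusted over the list alone). This was the peptide transporter TAP1 (2.13, SE 0.51, adjusted p = 0.0362), which did not pass under limma voom or without either library of CD39/CD46/CD55/TBM. Adjusted p values of TAP1 ranged from 0.000108 to 0.157 over the alternatives. B2M had 4152 and 6680 counts in CD39/CD55 and 4273 and 7464 in CD39/CD46/CD55/TBM (adjusted p = 0.266).

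Macrophage and monocyte markers and pan-leukocyte genes of the pig had low medians in the transplanted kidneys of both genotypes. C1QC, a complement C1q chain made by macrophages, had 152 counts in the untransplanted CD39/CD55 kidney and 158 in the untransplanted CD39/CD46/CD55/TBM kidney and none in either transplanted kidney, at least 45.7-fold and 43.1-fold lower (adjusted p = 0.00098). The signalling adaptor TYROBP fell from 150 to 1 and from 116 to 6 counts (log2 fold change -4.95, SE 0.75, adjusted p = 0.00441). Of 27 macrophage and monocyte markers, 9 fell and 1 rose (15 and 2 adjusted over the list alone), and the medians were -1.78 and -1.41. The member that rose was GPNMB, from 1049 to 3290 and from 731 to 5120 counts, which did not pass without the untransplanted CD39/CD46/CD55/TBM library (adjusted p 8.61e-06 to 0.0619 over the alternatives). Of 22 pan-leukocyte genes, 4 fell and none rose (8 and 0 adjusted over the list alone), with medians of -1.64 in CD39/CD55 and -1.49 in CD39/CD46/CD55/TBM, or -1.39 with genes of no count at their bound. PTPRC, which encodes CD45, had 141 and 27 counts in CD39/CD55 and 120 and 31 in CD39/CD46/CD55/TBM (adjusted p = 0.0522), and CD68 had 36 and 11, and 29 and 23.

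MHC class II genes had medians of -2.08 and -1.43, and 5 of 11 fell with none rising (8 and 0 adjusted over the list alone). Which kidney cells carried these transcripts cannot be told from these counts. SLA-DRA fell from 1612 to 324 and from 1335 to 272 counts (log2 fold change -2.09, SE 0.41, adjusted p = 0.0159). The 13 measured T and NK cell markers had medians of -1.50 and -0.60 and the 8 measured B and plasma cell markers 0.04 and -0.32, with none past the test in either adjustment. CD3E had 3 to 5 counts in each library and MS4A1 at most 4. Of the neutrophil markers, S100A8 had 12 and 0 counts in CD39/CD55 and 19 and 5 in CD39/CD46/CD55/TBM, and S100A12 had 11 and 0, and 16 and 2. These are counts on pig genes, and cells of the recipient were not measured as such.

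**Figure D2:**
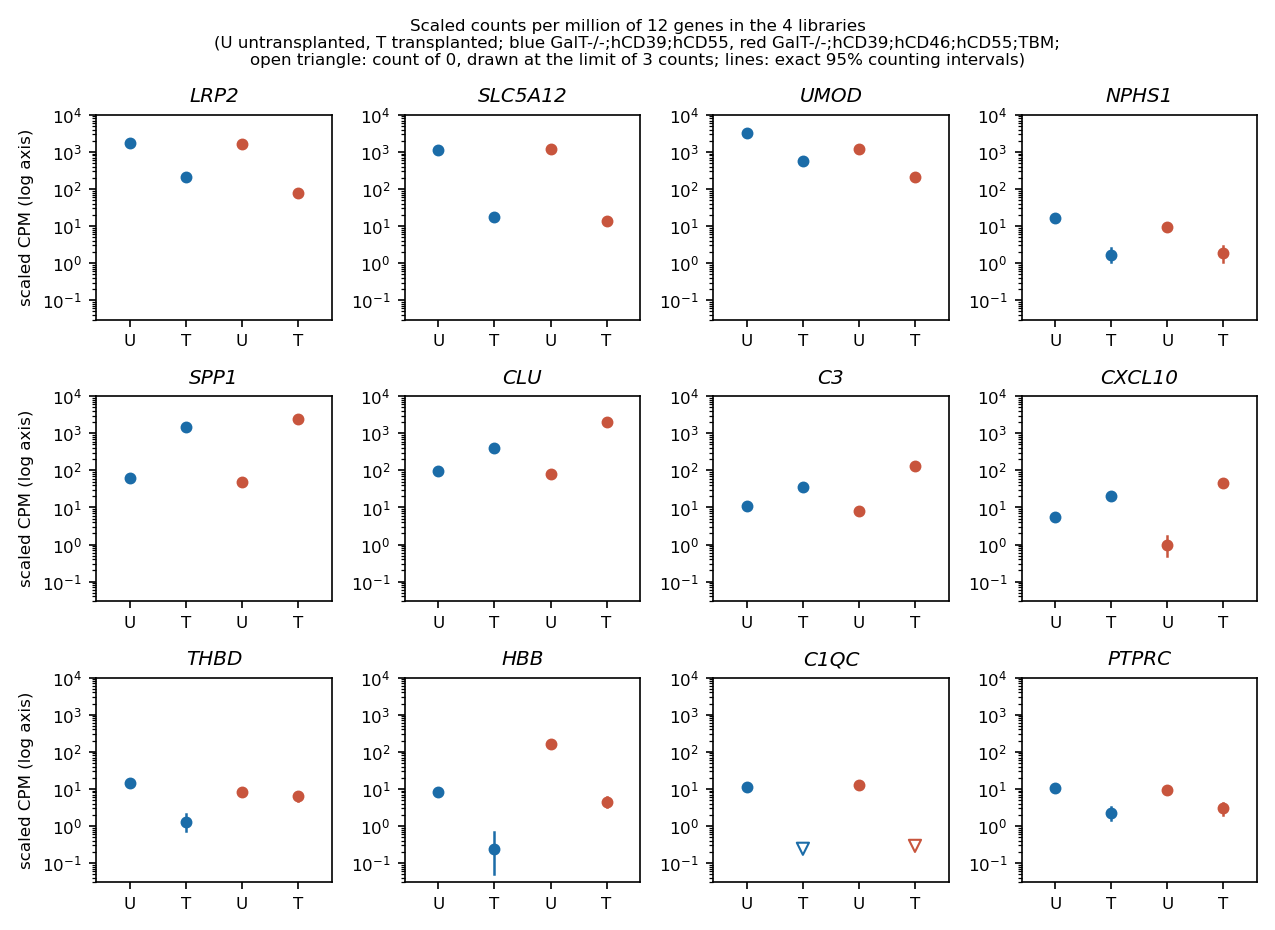
Scaled CPM on a log axis for 12 genes in the 4 libraries (U untransplanted, T transplanted), with CD39/CD55 in blue and CD39/CD46/CD55/TBM in red, exact 95% counting intervals as lines where wider than the point, and open triangles at the limit of 3 counts where no count was found. C1QC has no count in either transplanted kidney, and THBD has 16 counts in the transplanted CD39/CD55 kidney against 65 in the transplanted CD39/CD46/CD55/TBM kidney.

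Complement and coagulation genes went both ways. Among 27 complement components and regulators, 4 rose and 4 fell (9 and 7 adjusted over the list alone). The 4 that rose were C1S, C3, C9 and CLU, of which CLU is also on the tubular injury list. The 4 that fell were C3AR1 and the C1q genes C1QA, C1QB and C1QC. The C1q genes are also on the macrophage and monocyte list, so their fall is counted in both lists. C3, the central component (chromosome 2, 72431470 to 72471622), rose from 153 to 431 and from 101 to 1343 counts (log2 fold change 3.10, SE 0.59, adjusted p = 0.0133), while C1QB fell from 136 to 1 and from 152 to 2. The list's medians were 0.79 and 0.50. Among 30 coagulation and fibrinolysis genes, 4 rose and 2 fell (8 and 2 adjusted over the list alone), with medians of -0.24 and 0.34. The fibrinogen genes FGB, FGG and FGA rose, FGB from 122 to 1535 and from 117 to 765 counts (log2 fold change 3.45, SE 0.46, adjusted p = 0.00234). FGA had 0 and 52 counts in CD39/CD55, at least 19.2-fold higher, and 1 and 63 in CD39/CD46/CD55/TBM. The anticoagulant genes PROC (protein C) and SERPINC1 (antithrombin) fell, PROC from 822 to 24 and from 380 to 14 counts (-4.76, SE 0.55, adjusted p = 0.00107). The acute phase gene SAA3 rose from 6 to 142 and from 10 to 819 counts (6.19, SE 0.88, adjusted p = 0.0033).

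Endothelial markers had medians of -1.09 in CD39/CD55 and -0.52 in CD39/CD46/CD55/TBM, and 1 of 23, the angiopoietin receptor TEK, fell (the same number adjusted over the list alone). TEK did not pass when any library other than that of the transplanted CD39/CD55 kidney was left out (adjusted p 0.00181 to 0.0872 over the alternatives). VWF had 71 and 44 counts in CD39/CD55 and 54 and 59 in CD39/CD46/CD55/TBM. Extracellular matrix and fibrosis genes had medians of 0.02 and 0.23, with 2 of 48 up and 2 down (3 and 4 adjusted over the list alone). COL8A1 rose from 48 to 318 and from 67 to 365 counts (2.79, SE 0.47, adjusted p = 0.00707), and COL15A1 fell from 953 to 56 and from 542 to 33 (-3.86, SE 0.48, adjusted p = 0.00181). COL1A1, the main fibrillar collagen gene, had 3970 and 947 counts in CD39/CD55 and 1844 and 340 in CD39/CD46/CD55/TBM (adjusted p = 0.0567), and FN1 had 548 and 702, and 335 and 788. Proliferation genes had medians of -0.65 and -0.36, and TYMS, an enzyme of thymidylate synthesis, was the 1 of 33 that fell (-2.14, SE 0.41, adjusted p = 0.0145; also 1 adjusted over the list alone).

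Among the remaining lists, 2 of 24 chemokines and cytokines, CXCL10 and CXCL16, rose (also 2 adjusted over the list alone), with medians of 0.13 and 0.19, or 0.22 in CD39/CD55 with genes of no count at their bound. CXCL16 did not pass when any library other than that of the transplanted CD39/CD55 kidney was left out (0.000954 to 0.206). Immediate early and heat shock genes had medians of -0.28 and -0.17, and none of 32 passed over all genes, but 1 rose and 4 fell adjusted over the list alone. Glucocorticoid induced genes had medians of 0.05 and -0.44, and MT1A was the 1 of 17 that fell (1 up and 1 down adjusted over the list alone). FKBP5, which is induced by glucocorticoids, had 2026 and 6186 counts in CD39/CD55 and 2096 and 4148 in CD39/CD46/CD55/TBM (adjusted p = 0.0833). Erythrocyte genes had medians of -0.44, or -0.42 with genes of no count at their bound, and -0.32, and 2 of 10 fell in either adjustment, HBB and HBQ1. HBB, beta globin, had 110 and 3 counts in CD39/CD55 and 2114 and 46 in CD39/CD46/CD55/TBM, and did not pass under DESeq2's Wald test, limma voom or without the untransplanted CD39/CD46/CD55/TBM library (adjusted p 7.11e-16 to 0.157 over the alternatives). HBQ1 did not pass under limma voom or without the untransplanted CD39/CD55 library (8.54e-05 to 0.133). Adipocyte markers had medians of -1.59 and -1.09 (1 of 13 down, GPD1, and 1 up and 6 down adjusted over the list alone), muscle markers -0.64 and -0.72 (1 of 13 down, ACTA2, in either adjustment), and the 5 measured adrenal cortex markers -0.05 and 0.78 with none past the test in either adjustment. GPD1 and ACTA2 did not pass without the untransplanted CD39/CD55 library, nor GPD1 without the transplanted CD39/CD46/CD55/TBM library (up to 0.138 for GPD1 and 0.229 for ACTA2). Of the urothelium markers, UPK3A had 22 and 10 counts in CD39/CD55 and 31 and 19 in CD39/CD46/CD55/TBM.

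Within single genotypes, 2395 genes were called higher and 2495 lower in the transplanted CD39/CD55 kidney, and 2885 and 2957 in the transplanted CD39/CD46/CD55/TBM kidney. Under total-count scaling these numbers were 2949 and 2058, and 3146 and 2764, so the balance of higher and lower depends on the scaling. The 2 comparisons share no library. Genes called higher in both numbered 1068, where 380.3 would be expected of independent lists, and genes called lower in both numbered 1386, where 406.1 would be expected. Opposite calls were found for 75 and 56 genes. Across genes, which are not independent replicates, the 2 changes correlated with r = 0.56 and rho = 0.55. Of the 2454 genes with calls in the same direction, 58.7% had the larger absolute log2 ratio in CD39/CD46/CD55/TBM. For scale, 26.9% of genes were called in CD39/CD55 and 32.2% in CD39/CD46/CD55/TBM, against 16.1% between the untransplanted and 22% between the transplanted kidneys of the 2 genotypes.

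The difference between the 2 transplantation changes bears on the choice of genotype. The hypoxia and glycolysis, tubular injury, endothelial activation, MHC class I and coagulation lists were among those with the higher median ratio in CD39/CD46/CD55/TBM, and the proximal tubule, fatty acid oxidation and ribosomal protein lists among those with the lower. THBD was lower after transplantation in CD39/CD55, with a log2 ratio of -3.46 (95% counting interval -4.33 to -2.76). In CD39/CD46/CD55/TBM its ratio was -0.36 (-0.83 to 0.10), a difference of 3.10 (2.25 to 3.95). The THBD ratios between the genotypes were -0.85 in the untransplanted and 2.24 in the transplanted pair. Reads of the human thrombomodulin transgene, carried by CD39/CD46/CD55/TBM alone, may or may not fall on THBD. LDHA, lactate dehydrogenase, had log2 ratios of -0.83 in CD39/CD55 and 2.70 in CD39/CD46/CD55/TBM, a difference of 3.53 (3.21 to 3.86). The transcription factor gene IRF1 had -0.35 and 2.87, a difference of 3.22 (2.69 to 3.74). Part of this lay in the untransplanted pair, with log2 ratios between the genotypes of -1.65 there and 1.57 in the transplanted pair. The interferon response list as a whole had a median difference of 0.22, with 10 of 38 members called higher, 3 lower and 25 neither. Over all genes 1868 were called with a higher ratio in CD39/CD46/CD55/TBM and 2092 with a lower one. With 1 library per group this difference was not tested, and genotype goes with 4 or 6 weeks after transplantation.

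Hypoxia and glycolysis genes had medians of -0.28 in CD39/CD55 and 0.64 in CD39/CD46/CD55/TBM, and 11 of 25 were called with the higher ratio in CD39/CD46/CD55/TBM and none with the lower. The median difference of 0.95 lay above every matched random list, and the median ratio between the genotypes was -0.48 in the untransplanted pair and 0.49 in the transplanted pair. HK2, hexokinase, was the 1 member that rose over both genotypes (also 1 adjusted over the list alone), from 17 to 51 and from 10 to 130 counts, and did not pass under limma voom or without the transplanted CD39/CD46/CD55/TBM library (adjusted p 2.2e-05 to 0.148 over the alternatives). Endothelial activation genes had medians of -0.08 and 0.57, with 6 of 15 called higher in the difference and none lower, and none past the test over both genotypes in either adjustment. ICAM1 had 368 and 585 counts in CD39/CD55 and 142 and 567 in CD39/CD46/CD55/TBM. Its counts differed mainly between the untransplanted kidneys (log2 ratio between the genotypes of -1.25, against 0.21 in the transplanted pair). The endothelial activation list as a whole differed more in the transplanted pair. Its median ratio between the genotypes was -0.11 in the untransplanted pair (3 of 15 called lower, none higher). In the transplanted pair it was 0.63 (5 of 15 called higher, none lower). MHC class I and antigen processing genes had medians of 0.24 and 1.13, with 5 of 18 called higher in the difference and none lower, although reads shared among SLA class I genes make single members uncertain. Their median ratio between the genotypes was -0.44 in the untransplanted pair and 0.50 in the transplanted pair, so part of this difference lay in the untransplanted pair. Tubular injury genes were called higher in the difference for 13 of 35 and lower for none. LCN2 had a difference of 3.27 (2.40 to 4.14), C3 2.38 (1.98 to 2.77) and CXCL10 3.64 (2.75 to 4.53). For CXCL10 the larger part of this lay in the untransplanted pair, with log2 ratios between the genotypes of -2.48 there and 1.17 in the transplanted pair. The same ratios were -1.01 and 2.27 for LCN2 and -0.48 and 1.90 for C3. Coagulation and fibrinolysis genes had a median difference of 0.58, or 0.61 with genes of no count at their bound, with 7 of 30 called higher and 1 lower. Other lists with a median difference above the middle 95% of random lists were macrophage and monocyte markers (0.54), MHC class II (0.64), collecting duct (0.43), podocyte and glomerulus (0.44), mitochondrially encoded (0.65) and nuclear oxidative phosphorylation genes (0.23), and below it lay glucocorticoid induced genes (-0.49). For MHC class II the median ratio between the genotypes was -0.86 in the untransplanted pair and 0.01 in the transplanted pair. Its difference thus lay mainly in the untransplanted pair. For macrophage and monocyte markers these medians were -0.08 and 0.69, and for nuclear oxidative phosphorylation genes -0.47 and -0.30. The 10 antigen and transgene related pig genes had medians of -0.46 and 0.42, with 5 called higher in the difference and none lower, and none past the test over all genes (1 down adjusted over the list alone).

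Among single genes of the proximal tubule and fatty acid oxidation lists with the lower ratio in CD39/CD46/CD55/TBM were PCK1, FBP1 and CAT. PCK1, an enzyme gene of gluconeogenesis, went from 90982 to 47943 counts in CD39/CD55 and from 31480 to 2834 in CD39/CD46/CD55/TBM, a difference of -2.41 (-2.47 to -2.35). FBP1 had a difference of -2.73 (-2.84 to -2.61) and the peroxisomal enzyme gene CAT -1.72 (-1.81 to -1.64). Over the list, 15 of 46 proximal tubule genes were called lower in the difference, 4 higher and 27 neither, and of 28 fatty acid oxidation and peroxisome genes 8 lower, none higher and 20 neither. Ribosomal protein genes had a median of 0.67 in CD39/CD55 and -0.11 in CD39/CD46/CD55/TBM, and 17 of 48 were called lower in the difference and none higher, with none past the test over both genotypes in either adjustment.

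The untransplanted kidneys were compared between the genotypes to show how far they differed without a graft. The vitamin D catabolic gene CYP24A1 had 26 counts in CD39/CD55 and 1221 in CD39/CD46/CD55/TBM, a log2 ratio of 5.64 (95% counting interval 5.11 to 6.29). CYP27B1, the enzyme that activates vitamin D, had 1704 and 63 counts, a ratio of -4.63 (-5.03 to -4.28). CYP4A24, a cytochrome P450 gene, had 4 and 1631 counts, a ratio of 8.61 (7.43 to 10.67). HBB had 110 and 2114 counts (4.38, 4.11 to 4.67). The fatty acid synthesis genes FASN and SCD had ratios of -2.37 and -2.81, and KIRREL3 -3.86. In this pair 1483 genes were called higher in CD39/CD46/CD55/TBM and 1433 lower.

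Among the lists, the 13 mitochondrially encoded genes had a median ratio of 0.79 in this pair, with 6 called higher and none lower. Immediate early and heat shock genes, which respond to handling and stress, had a median of 0.55 with 9 of 32 called higher and 1 lower. ATF3 had 300 and 1398 counts and HSPA8 1184 and 3673. Lower medians in CD39/CD46/CD55/TBM were found for MHC class II genes (-0.86, 4 of 11 called lower and none higher), adipocyte markers (-0.71, 5 of 13 lower and 2 higher), hypoxia and glycolysis genes (-0.48, 7 of 25 lower and none higher), nuclear oxidative phosphorylation genes (-0.47, 6 of 36 lower and none higher), extracellular matrix genes (-0.44, 6 of 48 lower and 2 higher), MHC class I and antigen processing genes (-0.44, 2 of 18 lower and 1 higher) and interferon response genes (-0.31, 7 of 38 lower and 2 higher). Proximal tubule genes had a median of -0.16, with 3 called higher and 7 lower.

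In the transplanted pair, 1996 genes were called higher in the CD39/CD46/CD55/TBM kidney at 6 weeks and 2006 lower, relative to the CD39/CD55 kidney at 4 weeks, a balance that depends on the scaling. JPH2, a junctional membrane protein gene, had 23 and 917 counts, a log2 ratio of 5.54 (4.98 to 6.24). GBP1, an interferon-induced GTPase, had 88 and 784 counts (3.41, 3.09 to 3.75), and LDHA 191 and 1191 (2.89, 2.68 to 3.13). Erythropoietin, EPO, had no count in CD39/CD55 and 34 in CD39/CD46/CD55/TBM, at least 13.6-fold higher. Lower were CYP2C49, with 519 and 4 counts (-6.61, -8.64 to -5.40), PCK1 with 47943 and 2834 (-3.82, -3.88 to -3.77) and HAAO with 2627 and 204 (-3.43, -3.64 to -3.22). CREB3L3, a transcription factor gene, had 49 and 0 counts, at least 13.7-fold lower.

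By list, tubular injury genes had a median ratio of 0.90 in the transplanted pair, with 14 of 35 called higher and 1 lower, and proliferation genes 0.79, with 10 of 33 higher and 1 lower. TOP2A had 29 and 135 counts and CENPF 28 and 153, while MKI67 had 15 and 26. Immediate early and heat shock genes had a median of 0.80 (13 of 32 higher, 1 lower), macrophage and monocyte markers 0.69 (4 of 27 higher, 2 lower), podocyte and glomerulus genes 0.49 (3 of 22 higher, 2 lower) and hypoxia and glycolysis genes 0.49 (7 of 25 higher, none lower). Proximal tubule genes had a median of -0.95, or -0.92 with genes of no count at their bound, and 21 of 46 were called lower and 3 higher. Fatty acid oxidation genes had a median of -0.61, ribosomal protein genes -0.61 and adipocyte markers -1.03. Interferon response genes had a median of 0.00, with 6 of 38 called higher and 1 lower.

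**Figure D3:**
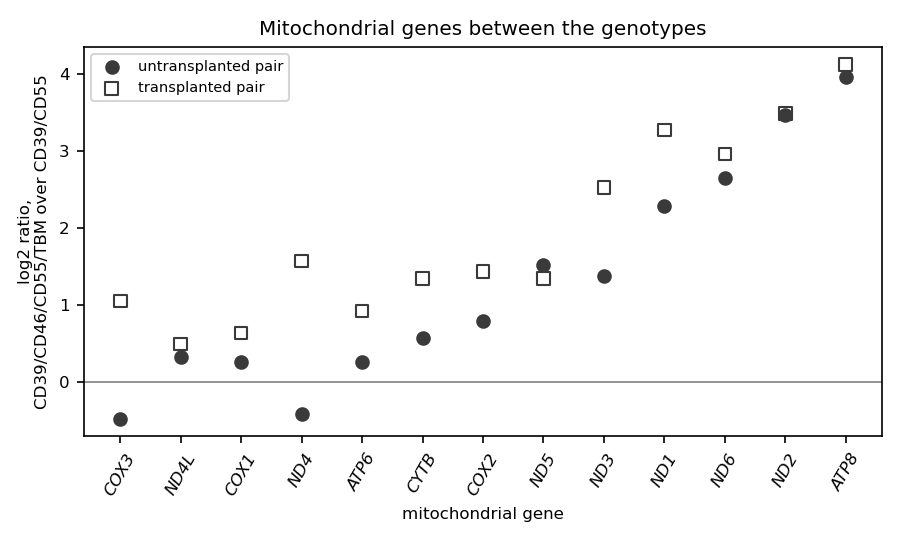
Log2 ratio of CD39/CD46/CD55/TBM over CD39/CD55 (y axis) for the 13 mitochondrially encoded genes (x axis, ordered by their mean), in the untransplanted pair (filled circles) and the transplanted pair (open squares), 1 library per group and without counting intervals. ATP8 lies at 3.96 and 4.12 and ND2 at 3.46 and 3.48, while COX3 lies at -0.48 and 1.05.

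Mitochondrially encoded genes were higher in CD39/CD46/CD55/TBM in the transplanted pair as well, with a median of 1.43 and 10 of 13 called higher and none lower. After transplantation their median log2 ratio was -1.03 in CD39/CD55, with 8 called lower and none higher, and -0.38 in CD39/CD46/CD55/TBM, with 1 lower and none higher, so the larger ratio in the transplanted pair goes with the lower values of the transplanted CD39/CD55 kidney. None passed the test of transplantation over both genotypes in either adjustment. ND2 had 23133 and 235440 counts in the untransplanted CD39/CD55 and CD39/CD46/CD55/TBM kidneys and 19469 and 182090 in the transplanted ones. When the genotypes were tested over both states, 2 libraries against 2, no gene passed edgeR's quasi-likelihood test in either direction (smallest adjusted p = 0.982), with 190 higher and 259 lower at an unadjusted p under 0.05. The genes with the smallest p were CYP4A24, CYP24A1, OSER1, ATP8 and ND2 among those higher in CD39/CD46/CD55/TBM and RNF125, CSPG4, FASN, KIRREL3 and the transfer RNA gene TRNAN-GUU among those lower. limma voom also called none, DESeq2's Wald test called 12 higher and 5 lower, and edgeR with treatment as a block called 133 higher and 171 lower.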

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

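Of the explanations weighed below, those of a general loss of low-expressed transcripts, of replacement by recipient cells, of more mitochondrial RNA of every gene and of the untransplanted kidneys alone were written down only after the result was seen.

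For 12 of the named genes the 2 genotypes' transplantation changes were called in opposite directions, and with 1 library per group the difference was not tested. Higher after transplantation in CD39/CD46/CD55/TBM and lower in CD39/CD55 were APLN (log2 difference 3.43, from -2.15 in CD39/CD55 and 1.28 in CD39/CD46/CD55/TBM), CIDEA (3.16, from -2.03 and 1.12), CKB (2.53, from -1.26 and 1.26), GDF15 (4.14, from -1.32 and 2.82), JPH2 (3.79, from -1.40 and 2.39), LYVE1 (4.05, from -2.40 and 1.65) and PFKFB3 (2.52, from -1.09 and 1.43). The untransplanted kidneys differed in some of these, with log2 ratios between the genotypes of -1.71 for APLN, -1.18 for CIDEA, -1.70 for CKB, -2.64 for GDF15 and 1.76 for JPH2. Part of the difference in the first 4 thus lies in the untransplanted pair. GDF15 had 3 counts in the untransplanted CD39/CD46/CD55/TBM kidney and LYVE1 2 counts in the transplanted CD39/CD55 kidney.

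The opposite pattern was found for CALB1 (-3.08, from 1.06 and -2.02), CYP24A1 (-2.43, from 1.05 and -1.38), PLET1 (-7.49, from 3.74 and -3.75), SLC26A4 (-3.97, from 2.65 and -1.32) and HMX2. HMX2 had 0 and 86 counts in CD39/CD55 and 70 and 28 in CD39/CD46/CD55/TBM, so its difference of -8.53 rests on the prior count and is no bound. All 5 had more counts in the untransplanted CD39/CD46/CD55/TBM kidney than in the untransplanted CD39/CD55 kidney.

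Low pig pan-leukocyte genes in both transplanted kidneys could come from smaller libraries. With counts thinned to the smallest total the median of the list was -1.69 in CD39/CD55 and -1.45 in CD39/CD46/CD55/TBM. The ratios were already scaled by library size, so thinning could hardly move the median, and this check decides nothing about library size. A general loss of low-expressed transcripts would lower random lists of like expression too, and their median in CD39/CD55 was 0.17. Recipient cells that replace the pig's blood cells, with reads that pig gene models may not count, predict a fall of erythrocyte transcripts as well, and HBB had a log2 fold change of -5.25 over both genotypes (adjusted p = 0.0353, and up to 0.157 over the alternatives). The erythrocyte list as a whole did not show it, since 2 of 10 members fell, its medians were -0.44 and -0.32, and HEMGN was called higher in both genotypes. A depletion of leukocytes predicts the leukocyte part too, so this explanation remains open.

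Higher mitochondrial counts in both CD39/CD46/CD55/TBM kidneys could be more mitochondrial RNA of every gene, but the mean log2 ratios of the 13 genes spanned 3.75, from 0.29 in COX3 to 4.04 in ATP8. A mitochondrial sequence or preparation difference that goes with the genotype predicts the same ranking of genes in the untransplanted and the transplanted pair, and Spearman's rho was 0.77 across genes, which are not independent replicates. Sequence, preparation and genotype go together in the design, so a biological effect of the genotype cannot be told from them here.

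Hypoxia and glycolysis genes, with the higher ratio after transplantation in CD39/CD46/CD55/TBM, might differ only because the untransplanted kidneys did, but in the transplanted pair their median was 0.49, at percentile 99.75 of random lists. A smaller share of proximal tubule RNA in that kidney would raise distal nephron genes equally. The list's median exceeded that of 52 distal nephron genes by 0.28 (95% bootstrap interval over genes -0.16 to 0.80), so this remains open. The biological contrast in the design, genotype, goes with 4 or 6 weeks after transplantation.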

How the results depend on the processing

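No alternative was chosen after the data were seen, and the explanations tested after the result was seen are named in the part above.

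No log2 ratio called in a named gene, and no fold change past the threshold in one, changed sign under the alternatives run for it. Of the list medians 14 did, 6 under total-count scaling and 8 with the filter of 50 counts, none of them in a list outside the middle 95% of random lists. Under total-count scaling the medians of endothelial activation genes and adrenal markers in the CD39/CD55 change went from -0.08 to 0.06 and from -0.05 to 0.09, and in the transplanted pair those of interferon response and MHC class II genes from 0.00 and 0.01 to -0.09. With at least 50 counts the largest were T and NK cell markers in the untransplanted pair (-0.63 to 0.22) and erythrocyte genes, which went from -0.32 to 0.14 in the CD39/CD46/CD55/TBM change, from 0.18 to -0.60 in the untransplanted pair and from -0.04 to 0.78 in the difference. Of the 648 fold changes recomputed for genes past the threshold, 40 lost it, and of 2622 log2 ratios 64 moved beyond their counting interval, all under total-count scaling. Of 610 list medians 23 moved, 17 with the filter of 50 counts and 6 with a prior count of 5. Scaling by total counts shifted the median ratio by 0.14 in the CD39/CD55 change, where 58.9% of calls were then higher instead of 49.0%, and by -0.10 between the transplanted kidneys, where 1632 genes were then called higher and 2381 lower (40.7% higher instead of 49.9%).

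Under the rule that the whole interval lies beyond 2-fold, 928 genes were called higher and 1454 lower in the CD39/CD55 change, 1396 and 1734 in the CD39/CD46/CD55/TBM change, 482 and 576 between the untransplanted kidneys, 752 and 819 between the transplanted kidneys, and 621 and 813 in the difference of the changes. Under the 4-fold rule these were 778 and 772, 873 and 1100, 315 and 280, 412 and 531, and 575 and 665. With at least 50 counts, which tests fewer genes, 1446 were called higher and 1992 lower in the first of these, 1868 and 2423 in the second, 953 and 1039 in the third and 1264 and 1509 in the fourth, so that 42.1% of calls in the CD39/CD55 change and 43.5% in the CD39/CD46/CD55/TBM change were higher instead of 49.0% and 49.4%. The correlation of the changes was r = 0.42 and rho = 0.42 without a filter and r = 0.66 and rho = 0.62 with at least 50 counts.

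For transplantation over both genotypes, where edgeR gave 225 higher and 493 lower, DESeq2's Wald test gave 431 and 865, genotype as a block 1124 and 1681, and no filter 543 and 1035. Leaving out 1 library gave 188 to 1055 higher and 410 to 1374 lower, the most without the transplanted CD39/CD55 kidney (1055 and 1374), and 371 higher without the untransplanted CD39/CD46/CD55/TBM kidney. For genotype over both states, where edgeR gave 0 and 0, DESeq2's Wald test gave 12 and 5, treatment as a block 133 and 171, and leaving out 1 library 0 to 9 and 0 to 3, with 9 and 3 without the untransplanted CD39/CD55 kidney, 1 and 3 without the transplanted CD39/CD55 kidney, and 3 and 0 without the transplanted CD39/CD46/CD55/TBM kidney. A lone library left on 1 side is assumed to vary like the others. The cause of these shifts was not tested, apart from fewer genes or libraries by construction. Depth limits CXCL9, IDO1, CD3E and MS4A1, which had 6 counts or fewer in every library.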

Other observations

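Nothing in this part was a test chosen after the result was seen, and single genes picked after their values were seen are named as such.

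Some genes with the smallest p in edgeR's test of genotype over both states had ratios of the same direction in both states. Choosing genes by that test favours like ratios in the 2 states, and no gene passed it. RNF125, a ubiquitin ligase gene, had 983 and 960 counts in the untransplanted and transplanted CD39/CD55 kidneys and 158 and 156 in the CD39/CD46/CD55/TBM kidneys, so its ratio between the genotypes was alike in the untransplanted pair (-2.52) and the transplanted pair (-2.36). KIRREL3 had ratios of -3.86 and -3.14, CSPG4 -3.81 and -2.95, and OSER1 2.82 and 2.10. For the vitamin D genes the ratio between the genotypes was smaller in the transplanted pair, -4.63 and -2.30 for CYP27B1 and 5.64 and 3.21 for CYP24A1. HMOX1, heme oxygenase, had 1102 and 135 counts in the untransplanted CD39/CD55 and CD39/CD46/CD55/TBM kidneys, while HBB was the higher in the second.

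SULT2A1, a sulfotransferase gene, had 126 counts in the transplanted CD39/CD55 kidney and at most 3 in the other libraries. The endothelial adhesion gene SELE had 28 counts in the transplanted CD39/CD46/CD55/TBM kidney and at most 1 in the others. TNFRSF17, a plasma cell receptor gene, had 183 and 152 counts in CD39/CD55 and 60 and 14 in CD39/CD46/CD55/TBM. The long non-coding RNA LOC102163816, chosen after its values were seen, had 30003 and 99525 counts in CD39/CD55 and 165430 and 459371 in CD39/CD46/CD55/TBM.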
